A study of Mus musculus with 29 samples.

How the data were processed

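Chromatin accessibility was measured by ATAC-seq in 29 libraries of mouse neutrophils, sorted as CD11b+CD115-Ly6G+ cells and parted by CD101 into a mature (CD101+) and an immature (CD101-) fraction. The deposited table gives raw counts, which the authors made per library over 1 peak set shared by all libraries and left without normalization. Per the labels, the authors used cutadapt 2.5, FastQC, BWA 0.7.17, SAMtools, Picard, MACS2 2.1.1.20160309, bedtools, edgeR and deepTools 3.1.0 with build mm10 (GRCm38), and the labels do not state the order of these steps. The deposited table also gives the width of each peak in bp, which equals the end minus the start plus 1, so that the coordinates are 1-based and closed; widths ran from 151 to 6085 bp with a median of 484 bp. Of the 92133 peaks, 90884 lay on primary chromosomes.

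Libraries were grouped by tissue, mouse and fraction as the titles and cell type labels state. This gave 27 libraries in 10 groups. The other 2, spleen libraries with replicate number 2, carry a title that names one fraction and a cell type label that names the other, and they were left out of all groups. Total counts per library ran from 12031772 to 55237415, and 3 counts, taken as the floor of detection, correspond to 0.0543 to 0.249 CPM; such limits cover counting error only, and PCR copies without molecular identifiers are not independent molecules. The precision of a fold change is given as its standard error, from the spread between the libraries of all groups.

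Peaks were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit) in R 4.3.3 on TMM-scaled counts, in 1 fit of all 27 libraries with a mean per group, so that groups of 2 borrow the spread of the others. Adjusted p-values follow Benjamini and Hochberg over the tested peaks, with a threshold of 0.05. The filter on low counts (filterByExpr) removed 0 peaks. The 15 pairs of groups and 2 differences between maturity effects, the tests, the gene lists, the naming of genes and most alternatives were chosen before the data were examined. Within each comparison the libraries of the 2 groups carry no stated pairing; whether libraries of the same replicate number deviated together was checked by the correlation of their residuals across peaks.

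For values per gene, counts were summed over the peaks linked to it. A peak was linked to the protein-coding gene of GRCm38 whose body holds its midpoint (if several, the one with the nearest end), otherwise to the nearest gene body within 50 kb. The plan had been to link by the nearest transcription start, which the gene table, having no strand, does not give. In this way 79432 peaks were linked to 16498 genes, 51154 of them within a gene, and 946 of these within several genes, whose counts cannot be parted. Gene values were tested with edgeR as above.

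The 20 gene lists covered azurophil granule and early genes, specific granules, late maturation, cell cycle, tumour neutrophils, hypoxia and glycolysis, NF-kB and inflammation, interferon-stimulated genes, AP-1 and stress, immunosuppression and angiogenesis, lysosome and lipid, and trafficking and adhesion, besides markers of 8 other cell types (monocytes and macrophages, eosinophils, T and NK cells, B and plasma cells, erythroid cells and megakaryocytes, progenitors, tumour epithelium, and stroma and endothelium). The tumour neutrophil list holds genes of earlier studies, some of this model, and shares 17 of its 20 genes with other lists. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, in 1 direction.

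Genes and peaks were named by a fixed rule. In each comparison the peaks with an adjusted p under 0.05, a fold of at least 2, replicate ranges that do not overlap and a mean above the median peak were ranked, 1 per gene, and the 8 with the largest rise and the 8 with the largest fall were eligible, as were up to 4 members per list with the smallest adjusted p. Cd101, Ly6g, Mpo, Ltf, Mmp9, Cxcr2, Cxcr4, Tnfrsf23, Vegfa, Arg1 and Cd274 were eligible in every comparison. Peaks with 3 counts or fewer in a group were not named, and the peaks at Tmem108 and Mapkapk3 and the gene Ptprc are named for their position, after their values were seen.

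A maturation score per library was the mean log2(CPM + 1) over the peaks higher in mature WT marrow cells minus the mean over the lower ones, with peaks chosen by a fit of the WT libraries alone. A tumour score was built likewise on peaks that differed between tumour and marrow in one fraction and was read in the other. Groups were compared by exact two-sided permutation tests, whose smallest p is 0.1 for 3 libraries against 3 or 2 and 0.333 for 2 against 2.

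The alternatives were DESeq2 size factors, total counts in peaks and loess offsets for scaling; no filter and a stricter one (a mean of at least 5 CPM); DESeq2 1.42.0 as the test; a fit of only the groups compared; the replicate number as a block, with all groups or with only those compared; autosomes only; a fold of at least 2; peaks within 1 kb of a gene body; and each library left out in turn. For the scores they were a pseudocount of 0.1, total counts, no fold minimum and the 500 peaks with the smallest p in each direction. Peaks open outside the tumour and peaks off chromosomes 1 and 9 served for some comparisons. Windows of 5 Mb were chosen after the data were seen, where immature marrow calls against WT exceeded chance at an adjusted p under 1e-05. List medians were also set against 10000 sets of genes of like marrow level (up to 200 ranks on each side), and differences between lists were tested by 100000 random exchanges of their members. Both treat genes as independent and leave out the spread between libraries. Splits of the libraries other than the real one were fitted for comparisons with 3 libraries per group, all 10 for a pair of groups and 40 (the real one and random draws) for a difference between maturity effects.

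The tests were tested on simulated data. Of 100 peaks changed 2-fold among 20000, 36 were found with the depth of the WT groups and 23 with that of the spleen groups of 2. At 4-fold these numbers were 78 and 62. The spread of each peak was taken over all groups, so that these numbers do not cover a group with a wider spread of its own. Of 200 peaks changed 4-fold among 5000, 199 or 200 were found under each scaling, block and DESeq2, with at most 14 false calls. These libraries were simulated at equal depth, the changed peaks had high counts, and as many rose as fell. The scalings were therefore bound to give like results, and their differences on the real data were not tested in this way. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Left out for lack of a genome sequence were the content of motifs and the correction for GC, and for lack of strand the promoter peaks.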

Results

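Chromatin accessibility was profiled by ATAC-seq, which counts fragments from DNA open to a transposase, in neutrophils sorted as CD11b+CD115-Ly6G+ cells and split by the surface protein CD101 into a mature (CD101+) and an immature (CD101-) fraction. The cells came from the bone marrow, spleen, blood and tumour of mice carrying orthotopic pancreatic tumours, and from the bone marrow of wild type (WT) mice. The tumours were grown from 10000 injected cells of FC1242L, a line derived from the KPC mouse model of pancreatic cancer, and were excised 6 weeks after injection. The 27 libraries with labels that fit each other fell into 10 groups of 3, except mature blood, immature spleen and mature spleen neutrophils with 2 each; the design text states 3 for mature blood, of which 2 are in the data. A further 2 spleen libraries carry a title and a cell type label that contradict each other, and they entered no comparison. Counts covered 92133 peaks of a set shared by all libraries. The total count per library ran from 12031772 to 55237415, and the 3 immature tumour libraries were the shallowest, with 12031772 to 13789907. These 3 also had 10.037 to 13.49% of their counts in peaks outside the primary chromosomes, against 2.769 to 6.89% in the other groups. Coordinates are given on GRCm38 (mm10), 1-based. Log2 fold changes are written with their standard error (SE); gene values are summed over the peaks linked to a gene, and a count of genes or peaks that changed means an adjusted p under 0.05 in edgeR.

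Mature and immature neutrophils of WT marrow, the control of the series, were compared to see which chromatin changes with maturation without a tumour. Specific granule genes lost accessibility in mature cells: 14 of the 16 measured fell and 1 rose, with a list median of -1.84. Camp, the precursor of an antimicrobial peptide, had a log2 fold change of -3.13 ± 0.23 (SE, n = 3 per group). Ltf, which encodes lactoferrin, had -2.92 ± 0.33, Itgb2l -2.75 ± 0.23 and Cd177 -1.98 ± 0.17. Genes of late maturation moved the other way, with 15 of 22 higher and 0 lower (median 0.81). Il1b, the cytokine interleukin-1 beta, stood at +2.77 ± 0.25, Csf3r, the receptor for granulocyte colony-stimulating factor, at +2.07 ± 0.14 and Cxcr2, a chemokine receptor, at +1.38 ± 0.19. AP-1 and stress genes rose in 22 of 28 cases (Junb +1.89 ± 0.12, Atf3 +1.69 ± 0.11) and NF-kB and inflammatory genes in 22 of 30 (Bcl3 +1.61 ± 0.12). Interferon-stimulated genes rose in 18 of 27 (Slfn5 +2.26 ± 0.12, Oasl1 +1.92 ± 0.11), lysosome and lipid genes in 19 of 26 (Ctsd +1.08 ± 0.09) and trafficking genes in 14 of 22 (Itgax +1.28 ± 0.11). Azurophil granule and early genes fell in 10 of 15 cases (Fcnb -2.09 ± 0.21, Cebpe -1.36 ± 0.14). Progenitor markers fell in 7 of 12 (Gata2 -2.29 ± 0.24, Kit -1.99 ± 0.22). Cd274, which encodes the checkpoint ligand PD-L1, rose by 1.24 ± 0.14, whereas Cd101, the gene of the sort marker, had +0.16 ± 0.11 and did not pass the test (-0.18 when scaled to total counts and -0.14 with loess offsets).

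The peak with the largest rise among those named lay within Il1b on chromosome 2 from 129367929 to 129369180, at a mean of 6.24 ± 0.89 log2 CPM (counts scaled to library size; SD, n = 3) in mature and -1.22 ± 1.05 in immature cells. A peak within Ltf on chromosome 9 from 111034768 to 111035525 went from 4.42 ± 0.17 in immature to -0.64 ± 0.68 in mature cells. In all, 22691 peaks were higher and 19309 lower in mature WT marrow cells, 11541 and 13963 of them by at least 2-fold. For the 9 lists above, camera called a shift with adjusted p from 2.08e-07 to 0.032, and each call was lost with an estimated correlation (adjusted p from 0.355 to 0.636). The progenitor call was also lost without immature library 1 or mature library 3 (medians -0.72 and -0.62). Loess offsets ended the AP-1 (median 0.18), azurophil (-0.66, as in the main fit), late maturation (0.295), lysosome (0.24), progenitor (-0.32) and trafficking (0.47) calls. Total counts ended the azurophil and progenitor calls at larger medians (-1.0 and -1.02, against -0.66 and -0.68), and a block within these groups the azurophil call (-0.78). Adjusted over the list alone the counts were equal, except that 4 azurophil genes rose. The tumour neutrophil list (13 higher, 4 lower of 20), hypoxia and glycolysis (17 and 4 of 34), immunosuppression (11 and 9 of 26) and cell cycle (3 and 6 of 25) lists were not called. Nor were the markers of eosinophils, B cells, T and NK cells, monocytes and macrophages, erythroid cells, stroma or tumour epithelium. Scaled to total counts in peaks rather than by TMM (trimmed mean of M values), the median of all peaks moved from 0.144 to -0.288 and the split was 11093 higher and 31857 lower. Same-numbered WT libraries deviated together (r of 0.11 to 0.29 across peaks), and a fit blocked by replicate in these groups gave 50289 peaks.

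The same contrast in tumour-bearing mice asked whether maturation looks alike when a tumour is present. In their marrow 21430 peaks were higher and 18987 lower in mature cells, and in spleen 21954 and 16955. Over the 25504 peaks that changed at least 2-fold in WT marrow, 98.4% had the same sign in the marrow and 97.8% in the spleen of tumour-bearing mice, with slopes of 0.796 and 0.881. In marrow the specific granule list had 14 genes lower and 1 higher of 16 (Ltf -3.05 ± 0.33, Camp -2.41 ± 0.23), and late maturation genes rose in 15 of 22 cases, with 1 lower (Il1b +2.74 ± 0.25, Csf3r +2.30 ± 0.14). In spleen 13 specific granule genes fell and 1 rose (Ngp -3.67 ± 0.40, Ltf -3.16 ± 0.41). There 12 late maturation genes rose and 1 fell, and the AP-1 list rose in 23 of 28 cases (Junb +2.20 ± 0.15). NF-kB genes rose in 24 of 30 cases in both tissues (Icam1 +1.23 ± 0.09 in marrow, Tnfaip2 +1.88 ± 0.17 in spleen), interferon genes in 18 of 27 in both (Gbp2 +2.19 ± 0.18 in spleen) and AP-1 genes in 22 of 28 in marrow (Egr1 +1.55 ± 0.10). Hypoxia and glycolysis genes rose in 22 of 34 in marrow and 23 in spleen (Bnip3 +1.10 ± 0.11 and +1.54 ± 0.14). Cell cycle genes fell in 10 of 25 cases in marrow (Cdk1 -1.99 ± 0.21) and 12 in spleen (Mcm6 -0.82 ± 0.14). Camera called each of these lists in both tissues, and with them the azurophil, tumour neutrophil, lysosome, trafficking and progenitor lists. Every such call was lost with an estimated correlation (adjusted p from 0.381 to 0.465 in marrow, 0.347 to 0.618 in spleen). The replicate block ended the cell cycle call in marrow, with a median of -0.136 against -0.133, and the progenitor call in spleen. Loess offsets ended 5 calls in both tissues, with medians in marrow and spleen of -0.59 and -0.23 (azurophil), 0.21 and 0.02 (late maturation), -0.26 and -0.06 (progenitor), 0.31 and 0.23 (trafficking) and 0.30 and 0.29 (tumour neutrophil). In spleen they also ended the AP-1 (0.24) and lysosome (0.26) calls. Total counts ended the azurophil and progenitor calls in both tissues at larger medians: -1.03 and -0.91 in marrow, against -0.67 and -0.54, and -1.12 and -0.89 in spleen, against -0.61 and -0.37. They also ended the lysosome call in spleen (0.065). In spleen the groups fitted alone ended the azurophil and progenitor calls (-0.80 and -0.57), the block within them also the lysosome call (0.38), and DESeq2 size factors the progenitor call (-0.50). The hypoxia medians of 0.32 in marrow and 0.45 in spleen became -0.05 and -0.07 with total counts and -0.08 and -0.015 with loess offsets. In spleen, leaving out mature library 1 ended the azurophil, late maturation (median 0.57) and progenitor calls, leaving out mature library 3 the hypoxia (0.16) and tumour neutrophil (0.36) calls, and leaving out immature library 1 or 3 the progenitor call (-0.53 and -0.61). Adjusted over the list alone, 16 late maturation and 23 hypoxia genes rose in marrow and 4 NF-kB and 2 late maturation genes fell in spleen. Scaled to total counts the splits were 10791 higher and 32841 lower in marrow and 10867 and 32432 in spleen. The spleen groups held 2 libraries each, and the mature ones had the largest chi-square per degree of freedom of all pairs (23.55, against 12.63 or less). That measure grows with depth; their correlation was 0.944, against 0.893 to 0.938 in the 3 immature tumour pairs.

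In blood the mature and immature fractions lay closer together. Specific granule genes fell in 10 of 16 cases with 1 higher (Ngp -2.07 ± 0.36, Itgb2l -1.75 ± 0.26, Ltf -1.69 ± 0.37). Interferon-stimulated genes rose in 16 of 27 with 0 lower (Slfn5 +1.18 ± 0.13, Rsad2 +0.84 ± 0.13), AP-1 genes in 17 of 28 (Atf3 +0.76 ± 0.12) and NF-kB genes in 13 of 30 (Icam1 +0.76 ± 0.10). Csf3r had +0.73 ± 0.15 and Il1b +1.10 ± 0.26. In total 7165 peaks were higher and 5389 lower, but by at least 2-fold 1777 were higher and 3777 lower. Over the WT maturation peaks 85.9% had the same sign with a slope of 0.355. Camera called these 4 lists and the azurophil, lysosome and progenitor lists, and none with an estimated correlation (adjusted p from 0.308 to 0.525). For the first 4 the counts adjusted over the list alone were 12 lower, then 18, 19 and 17 higher. The azurophil call was lost without immature library 1 (median -0.22) and the progenitor call without mature library 2 (-0.30). Loess offsets ended the NF-kB (median 0.15 against 0.32), lysosome (0.08 against 0.22), azurophil (-0.23 against -0.29) and progenitor (-0.21 against -0.37) calls. Total counts ended the lysosome call (0.03) and, at larger medians, the azurophil (-0.485) and progenitor (-0.57) calls. The groups fitted alone ended the azurophil call (-0.38). Leaving out immature library 1 gave 6860 peaks, mature library 1 gave 4487 and mature library 2 gave 4729. With total counts the split was 1954 higher and 12555 lower, and with loess offsets 4177 and 4959.

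Mature and immature neutrophils were also compared inside the tumour, where 76.4% of the WT maturation peaks had the same sign with a slope of 0.271. NF-kB genes were higher in mature cells in 28 of 30 cases (median 1.09; Il1a +1.47 ± 0.12, Icam1 +1.42 ± 0.09). Hypoxia and glycolysis genes were higher in 29 of 34 (median 0.89; Aldoa +1.17 ± 0.10, Hk2, which encodes a hexokinase, +0.96 ± 0.06, Gapdh +0.93 ± 0.07). AP-1 and stress genes were higher in 23 of 28 (Nr4a3 +1.09 ± 0.08, Atf4 +1.04 ± 0.07) and trafficking genes in 19 of 22 (C5ar1 +1.33 ± 0.12, Ccr1 +1.37 ± 0.15). Late maturation genes rose in 19 of 22 (Il1r2 +2.07 ± 0.17, Il1b +2.13 ± 0.25), lysosome and lipid genes in 21 of 26 (Ctsz +1.28 ± 0.10, Plin2, a coat protein of lipid droplets, +0.93 ± 0.07). Immunosuppression and angiogenesis genes rose in 19 of 26 (Ptgs2 +1.92 ± 0.20, Tgm2 +1.16 ± 0.09) and interferon genes in 16 of 27 (Irf1 +0.93 ± 0.09). The tumour neutrophil list rose in 19 of 20 cases; 17 of its genes are also in other lists and some were picked in studies of this model, so it is not independent evidence. Tnfrsf23 had +1.10 ± 0.13, Cd274 +1.35 ± 0.14 and Vegfa, an angiogenic growth factor, +0.52 ± 0.08. Peaks open outside the tumour rose at large between these fractions, with a median of 0.503 (16646 higher, 3597 lower). A rise like that of Vegfa was thus not particular, and none of these lists was set against genes of like level here. Scaling changed some of these values, since Vegfa had +0.10 with total counts and -0.06 with loess offsets, Irf1 +0.07 with loess offsets, and the interferon list a median of -0.03 with total counts. Ltf, with -0.06 ± 0.31 (+0.61 without immature library 2), did not pass the test, and the specific granule list was not called (2 higher, 4 lower of 16). Markers of other cells were lower in the mature fraction: tumour epithelium 0 higher and 13 lower of 18 (median -1.55; Epcam -1.49 ± 0.19), erythroid cells 1 and 10 of 13, T and NK cells 3 and 9 of 17, B cells 0 and 6 of 12, and progenitors 0 and 8 of 12.

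In the tumour 20396 peaks were higher and 22145 lower in mature cells, 8126 and 18218 by at least 2-fold. A peak near Ptgs2 on chromosome 1 from 150108024 to 150110093 stood at 7.24 ± 0.01 log2 CPM in mature and 4.59 ± 0.24 in immature cells (SD, n = 3). Camera called all these lists except the specific granule one, and each call was lost with an estimated correlation (adjusted p from 0.14 to 0.356). The B cell call was also lost without immature library 2 (median -0.84) and the T and NK call without immature library 1 (-1.09) or mature library 3 (-0.94). Both were lost with loess offsets (-0.08 and -0.31) and, at medians of -1.59 to -0.81, with total counts, peaks within 1 kb of the gene body and the block within these groups. The T and NK call was lost with the groups fitted alone (-1.25). Loess offsets also ended the late maturation (0.11), erythroid (-0.43) and tumour epithelium (-0.52) calls. Adjusted over the list alone the counts were equal except 2 lower for hypoxia and 15 higher for interferon. The counts depended on the scaling: total counts gave 9979 higher and 42942 lower (median -0.727 against -0.221), and loess offsets gave 25875 peaks, 14147 higher and 11728 lower. DESeq2 size factors gave 22718 higher and 18432 lower. Among the peaks open outside the tumour, 16646 were higher and 3597 lower.

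A maturation score, the mean over 8928 peaks higher in mature WT marrow cells minus that over 16419 lower ones, gave each library of the tumour-bearing mice a value on the WT axis. Mature cells scored 1.62 ± 0.12 in marrow (SD, n = 3), 1.77 in both spleen libraries, 1.76 ± 0.01 in blood (n = 2) and 1.55 to 1.56 in the 3 tumour libraries. Each mature tumour library thus lay below each mature spleen and blood library. Immature cells scored -0.06 ± 0.02 in marrow and -0.08 to -0.07 in the 2 spleen libraries, but 1.09 ± 0.22 in blood and 0.93 ± 0.06 in the tumour (n = 3). The immature tumour libraries also carried raised markers of other cells (below), so that their score need not be that of neutrophils alone. They had 10.037 to 13.49% of counts off the primary chromosomes, a share that does not by itself mark other cells. Over the WT maturation peaks the change from immature marrow to immature tumour cells had the sign of maturation in 73% (2761 called in the opposite direction), against 95.7% (47) for immature blood cells. The difference between the fractions was 1.68 in marrow, 1.84 in spleen, 0.67 in blood and 0.62 in the tumour. With the 500 peaks of smallest p in each direction these differences were 3.874, 4.262, 1.734 and 1.619, and with a pseudocount of 0.1 they were 2.676, 2.884, 1.114 and 0.94. With no fold minimum the order of blood (0.604) and tumour (0.706) turned. In each tissue every mature library scored above every immature one, with an exact two-sided permutation p of 0.1, or 0.333 in spleen, the smallest these group sizes allow.

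**Figure D1:**
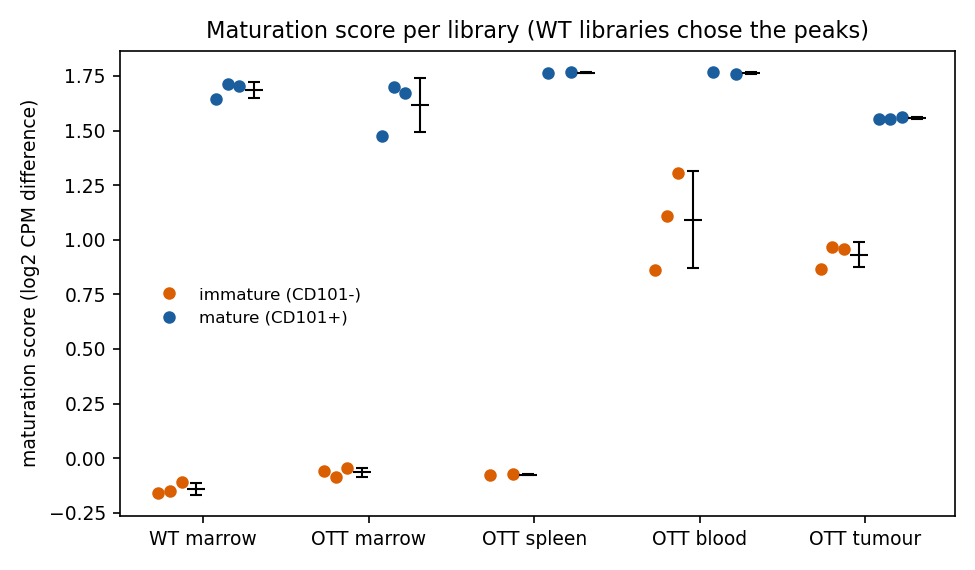
Maturation score of each library (difference of mean log2(CPM + 1) between peaks higher and lower in mature WT marrow neutrophils), by tissue; points are libraries, bars the mean of a group with error bars of 1 SD. Immature cells of blood and tumour lie between the immature and mature cells of marrow.

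Immature neutrophils of the tumour were compared with those of the marrow of tumour-bearing mice to describe the change between the site of production and the tumour. NF-kB and inflammatory genes were higher in the tumour in 26 of 30 cases (median 1.12; Ccl4, a chemokine, +2.61 ± 0.15, Ier3 +2.04 ± 0.14, Il1rn, which encodes the interleukin-1 receptor antagonist, +1.87 ± 0.13, Icam1 +1.37 ± 0.09). The tumour neutrophil list, not independent evidence, had 16 genes higher and 1 lower of 20, among them Hilpda, a lipid droplet protein induced by hypoxia, at +2.11 ± 0.18 and Cd274 at +2.02 ± 0.14. Specific granule genes fell in 14 of 16 cases with 0 higher (Lyz2 -2.59 ± 0.21, Padi4 -1.87 ± 0.13, Ltf -1.86 ± 0.32) and azurophil and early genes in 9 of 15 (Cebpe -1.99 ± 0.15). Late maturation genes fell in 14 of 22 with 3 higher (Mmp9 -1.25 ± 0.16, Cxcr2 -1.11 ± 0.20), and cell cycle genes in 11 of 25 (Mki67 -0.53 ± 0.06). A fall was common at open sites. Genes of the marrow level of the NF-kB list had a median of -0.28, and peaks open outside the tumour, a choice that favours lower ones, -0.832. The lists that fell were not set against genes of like level. Arg1, which encodes arginase, had +3.51 ± 0.37, Plin2 +1.23 ± 0.07 and Cd101 -1.01 ± 0.11. The hypoxia and glycolysis list moved both ways (10 higher, 13 lower of 34) and was not called. Markers of other cells rose as well: tumour epithelium 14 of 18 with 1 lower (median 2.70; Hnf1b +3.46 ± 0.28, Elf3 +3.88 ± 0.34), stroma and endothelium 11 of 17 (Pdgfrb +2.66 ± 0.24) and erythroid cells 10 of 13 (Ank1 +4.24 ± 0.37). Markers of monocytes and macrophages rose in 12 of 17 (Klf4 +2.82 ± 0.28). The T and NK (9 higher, 2 lower of 17), B cell (5 and 2 of 12) and eosinophil markers (3 and 3 of 10) were not called. In all 30643 peaks were higher and 27802 lower. A peak near Cxcl2, a neutrophil chemoattractant, on chromosome 5 from 90905993 to 90907577 stood at 5.53 ± 0.50 log2 CPM in the tumour and -2.69 ± 1.23 in marrow (SD, n = 3). Each of the 10 list calls by camera was lost with an estimated correlation (adjusted p from 0.328 to 0.639), and counts adjusted over the list alone were equal. The azurophil call was lost without tumour library 1 or 3 or marrow library 1 or 3 (medians -0.60 to -0.53), the late maturation call without tumour library 1 or 3 or marrow library 3 (-0.54 to -0.42), and the cell cycle call without tumour library 2 (-0.18). Loess offsets ended these 3 calls (medians -0.325, -0.16 and -0.05) and the erythroid (0.10) and stroma (0.25) calls. The replicate block ended the azurophil call at an equal median (-0.51), total counts the cell cycle call (-0.04), and peaks within 1 kb of the gene body both (-0.25 and -0.19). With total counts 38753 peaks were higher and 19232 lower.

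Mature neutrophils were compared between the same tissues. NF-kB genes were higher in the tumour in 28 of 30 cases with 0 lower (median 1.31; Ier3 +2.58 ± 0.15, Il1rn +2.57 ± 0.13, Tnfaip3 +1.68 ± 0.10, Icam1 +1.55 ± 0.09). The tumour neutrophil list, not independent evidence, rose in 19 of 20 (median 1.58; Hilpda +3.49 ± 0.19, Cd274 +2.03 ± 0.14, Tnfrsf23 +0.56 ± 0.13, Vegfa +0.36 ± 0.08). Immunosuppression and angiogenesis genes rose in 19 of 26 cases with 6 lower (Arg1 +3.57 ± 0.38, Il10 +2.38 ± 0.11, Mmp14, a membrane matrix metalloproteinase, +2.30 ± 0.14, Ptges, a prostaglandin E synthase, +1.43 ± 0.09). Hypoxia and glycolysis genes rose in 24 of 34 with 6 lower (Hk2 +0.86 ± 0.06, Pfkfb4 -1.21 ± 0.09), and lysosome and lipid genes in 15 of 26 with 5 lower (Tfec +2.46 ± 0.20, Ctsb, a cathepsin, +1.99 ± 0.12, Plin2 +1.66 ± 0.07). Cxcr2 (-1.70 ± 0.20), Csf3r (-1.66 ± 0.14) and Sell, the homing receptor L-selectin (-0.96 ± 0.14), were lower. The late maturation (4 higher, 10 lower of 22) and trafficking (4 and 11 of 22) lists that hold such genes were not called. Ltf (+1.12 ± 0.31) and Mpo, which encodes myeloperoxidase (+1.15 ± 0.15), were higher, but the specific granule (4 and 6 of 16) and azurophil (4 and 6 of 15) lists were not called. Tumour epithelium markers rose in 15 of 18 cases (median 1.24; Hnf1b +1.86 ± 0.27), stroma markers in 9 of 17 (Pdgfrb +1.87 ± 0.23), and monocyte and macrophage markers in 10 of 17 (Mertk +1.5 ± 0.15). In total 24484 peaks were higher and 23655 lower. A peak near Cxcr2 on chromosome 1 from 74161230 to 74162096 fell from 4.27 ± 0.27 log2 CPM in marrow to 0.72 ± 0.31 in the tumour (SD, n = 3). Each of the 8 list calls was lost with an estimated correlation (adjusted p of 0.0986 for the NF-kB and tumour neutrophil lists, 0.172 to 0.49 for the others); adjusted over the list alone, 25 hypoxia and 16 epithelium genes rose. With peaks within 1 kb of the gene body only, Vegfa had +0.14 and did not pass. The stroma and the monocyte and macrophage calls were lost with these peaks (medians 0.72 and 0.555, against 1.00 and 0.48) and with loess offsets (0.42 and 0.46). With total counts 32555 peaks were higher and 14659 lower.

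**Figure D2:**
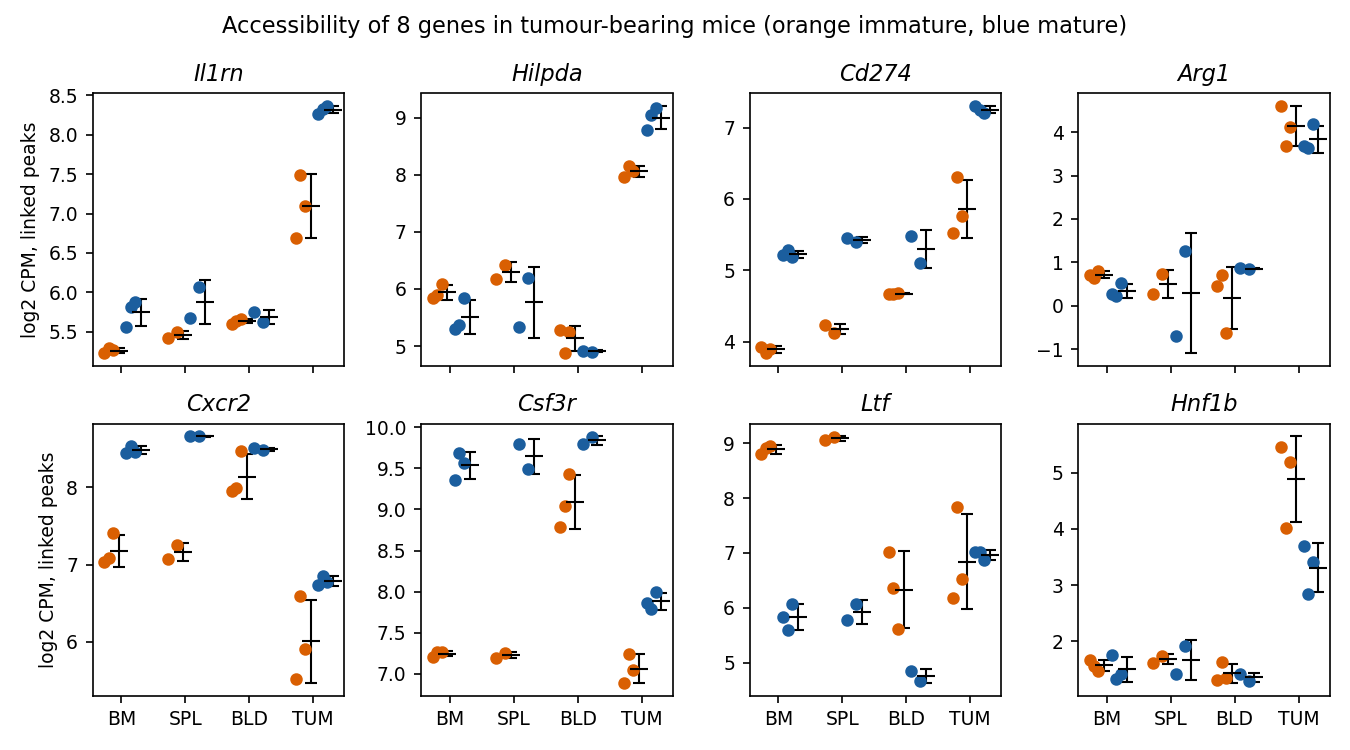
Gene-level accessibility (log2 CPM summed over linked peaks) of 8 genes in each library of tumour-bearing mice; points are libraries, bars the mean of a group and error bars 1 SD, with 2 or 3 libraries per group. Il1rn, Hilpda, Cd274 and Arg1 are higher and Cxcr2 is lower in both tumour groups than in marrow.

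Tumour and blood neutrophils were compared to set the tumour against circulating cells. Interferon-stimulated genes were lower in the tumour, in 20 of 27 cases with 2 higher in immature cells (median -0.86; Oas2 -1.91 ± 0.14, Irf7 -1.90 ± 0.12) and in 19 with 1 higher in mature cells (median -0.76; Oas2 -2.35 ± 0.14, Trim30a -1.68 ± 0.11). The interferon list was called higher in blood than in marrow in both fractions (below) and was not called between tumour and marrow. Its difference here thus need not be a fall in the tumour. Peaks open outside the tumour, a choice that favours lower ones, also had medians of -0.949 in immature and -0.562 in mature cells. NF-kB genes were higher in 18 of 30 with 3 lower in immature (Ccl4 +2.02 ± 0.15) and in 27 with 1 lower in mature cells (Il1rn +2.63 ± 0.16, Tnfaip3 +1.60 ± 0.11). The tumour neutrophil list, not independent evidence, rose in 12 and 19 of 20 cases, with Hilpda at +2.91 ± 0.19 in immature and +4.10 ± 0.24 in mature cells. Mature cells also gained immunosuppression genes (19 of 26, 5 lower; Mmp14 +2.58 ± 0.16, Il10 +2.53 ± 0.12), hypoxia and glycolysis genes (23 of 34, 5 lower; Hk2 +0.84 ± 0.07) and lysosome and lipid genes (15 of 26, 2 lower; Abca1, a cholesterol exporter, +2.32 ± 0.22). Immature cells lost late maturation genes (19 of 22, 1 higher; Csf3r -2.04 ± 0.14) and trafficking genes (17 of 22, 5 higher; Itgal, an integrin chain, -1.25 ± 0.12, but Ccrl2 +2.1 ± 0.20). Arg1 had +3.98 ± 0.38 in immature and +3.04 ± 0.43 in mature cells. Tumour epithelium markers rose in 16 of 18 cases in immature (median 2.79; Elf3 +3.65 ± 0.34) and in 15 in mature cells (median 1.32; Hnf1b +2.02 ± 0.32). Stroma markers rose in 14 and 8 of 17, and in immature cells erythroid markers in 10 of 13 and T and NK markers in 13 of 17. For immature cells 32205 peaks were higher and 26146 lower, for mature cells 23667 and 22579. The list calls were lost with an estimated correlation (adjusted p of 0.484 or 0.547 in immature cells, 0.14 to 0.493 in mature cells). In immature cells the NF-kB call was also lost without tumour library 2 (median 0.48) and the T and NK call without tumour library 1 (1.15), and loess offsets turned the T and NK median to -0.24 and ended the erythroid (0.59), stroma (0.42) and trafficking (-0.21) calls. The T and NK call was lost as well with total counts, peaks within 1 kb of the gene body and the groups fitted alone, at medians of 1.68, 1.36 and 1.15 (main 1.31). In mature cells the stroma call was lost without tumour library 2 (0.85) or blood library 1 (0.93). It was also lost with loess offsets (0.17) and, at medians of 0.80 to 1.13 (main 0.99), with total counts, the replicate block, peaks within 1 kb and the groups fitted alone. Adjusted over the list alone, 21 interferon genes fell in immature and 28 NF-kB genes rose in mature cells. With total counts the splits were 49221 higher and 15057 lower (median 0.904 against 0.245) and 35252 and 12246.

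Immature and mature cells shared much of their change in the tumour. Of the peaks higher in the tumour than in marrow, 19329 were called in both fractions, against 8143.3 expected if calls were independent, and of the lower ones 18066 against 7138.1; peaks are not independent, and these fractions share no libraries. Tumour epithelium markers rose in both fractions (medians 2.70 and 1.24). The immature libraries also had more counts off the primary chromosomes, which does not by itself mark tumour DNA, as the injected line is of mouse origin. Foreign DNA common to both fractions would raise this overlap and the score that follows. A tumour score, built on peaks chosen in one fraction and read in the other, was 2.27 above marrow in immature cells and 1.45 above in mature cells. Against spleen the differences were 2.28 and 1.21, and against blood 2.40 and 1.34 (exact two-sided permutation p of 0.1 each, the smallest these group sizes allow). With the 500 peaks of smallest p in each direction the 6 differences were 3.719, 3.668 and 4.204 in immature and 3.181, 2.472 and 3.142 in mature cells (marrow, spleen, blood). With a pseudocount of 0.1 they were 3.686, 3.689 and 3.747, and 2.349, 1.857 and 2.115.

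The maturity effect itself differed between tumour and marrow at 21925 peaks, 10122 with a more positive and 11803 with a more negative difference between mature and immature cells in the tumour. Specific granule genes, which fell with maturity in marrow, had a more positive effect in the tumour in 11 of 16 cases with 0 more negative (median 1.23), and azurophil genes in 7 of 15 with 1 more negative. The effect was also more positive for hypoxia and glycolysis genes (17 of 34, 3 more negative), NF-kB genes (13 of 30, 2 more negative), immunosuppression genes (9 of 26, 2 more negative) and the tumour neutrophil list (9 of 20, 2 more negative), and more negative for erythroid markers (7 of 13, 1 more positive; median -1.83). Of the tumour epithelium markers, 5 of 18 were more negative and 1 more positive, and that list was not called (median -0.98). These 7 calls were lost with an estimated correlation (adjusted p from 0.44 to 0.634); adjusted over the list alone, 10, 14, 18 and 10 genes of the tumour neutrophil, NF-kB, hypoxia and immunosuppression lists were more positive. Loess offsets ended the azurophil (median 0.59, against 0.67), immunosuppression (0.31 against 0.275), NF-kB (0.24 against 0.305), erythroid (-0.68) and tumour neutrophil (0.30 against 0.41) calls. Peaks within 1 kb of the gene body ended the azurophil (0.60), NF-kB (0.22) and tumour neutrophil (0.19) calls. With DESeq2 size factors the split was 15106 more positive and 10075 more negative. Among the peaks open outside the tumour it was 8565 and 2592, with a median of 0.298. The NF-kB (0.305) and immunosuppression (0.275) gene medians lay near this peak median, and the tumour neutrophil median (0.41) little above it. A more positive effect was thus not particular to these lists, which were not set against genes of like level here.

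Spleen cells were compared with marrow cells of the same fraction. In mature cells AP-1 genes were higher in spleen in 6 of 28 cases (14 adjusted over the list alone; Junb +0.59 ± 0.13, n = 2 against 3), NF-kB genes in 6 of 30 (7; Tnfaip2 +0.72 ± 0.15) and interferon genes in 4 of 27 (5; Gbp2 +0.90 ± 0.15). Among cell cycle genes 1 of 25, Hmgb2 (+0.47 ± 0.12), rose although that list's median was -0.13. Ly6g was lower in spleen (-0.57 ± 0.15). These 4 lists were called by camera and lost with an estimated correlation (adjusted p of 0.858 or 0.98). In mature cells 89 peaks were higher and 8 lower in spleen, and of the genes 634 were higher and 55 lower. The mature spleen libraries were unlike. Library 3 had 6.89% of its counts outside the primary chromosomes and a tumour score of -2.01, against 3.74% and -2.46 in library 1. Same-numbered libraries deviated together (r of 0.19 to 0.31 across peaks, 2 pairs), and a replicate block gave 296 peaks; total counts gave 1 higher and 3 lower, and the spleen and marrow groups fitted alone gave 0 (7064 unadjusted). The block within these groups gave 1102, and the stricter filter in the fit of all groups 1655. DESeq2, a separate test, gave 50015 peaks no adjusted p and called 1074 of the rest (7222 of these unadjusted), so that its counts cover fewer peaks than those of edgeR. The count in mature cells hung on single libraries, with 0 peaks without marrow library 1, 1 without marrow library 2, 0 without marrow library 3, 0 without spleen library 3 and 9530 without spleen library 1. The calls of Junb, Tnfaip2, Hmgb2 (+0.09) and Ly6g were lost without spleen library 3 or any of the 3 marrow libraries, and that of Gbp2 without spleen library 3 (+0.67) or marrow library 1 or 2. All 5 gene calls were lost with the groups fitted alone, those of Gbp2, Hmgb2 and Ly6g with the block within these groups, and those of Junb (+0.22 with loess offsets), Hmgb2 and Ly6g with DESeq2 size factors or loess offsets. Hmgb2 did not pass with total counts (+0.30) nor Ly6g with peaks within 1 kb. Fry called none of the cell cycle, interferon and NF-kB lists, and loess offsets ended the AP-1 (median 0.07) and cell cycle (-0.125, against -0.134) calls. The interferon call was lost without marrow library 3 (median 0.06), its median was -0.03 without spleen library 1 and with total counts, and the cell cycle median 0.03 without spleen library 3. In immature cells edgeR called 0 peaks, with 2696 at an unadjusted p under 0.05; DESeq2 called 1, the pair of groups fitted alone gave 482 and the block within them 2116. Camera called 7 lists in immature cells, each with 0 genes past the test and a median from 0.07 to 0.18, and none with fry or with an estimated correlation (adjusted p of 0.544 or 0.634). The interferon call was also lost with the replicate block (median 0.04), DESeq2 size factors and loess offsets, the late maturation call with loess offsets and peaks within 1 kb, and the erythroid call with the block within these groups. Leaving out any 1 of the 5 libraries ended at least 1 of these calls.

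Blood and marrow were compared to describe neutrophils that have entered the circulation. In immature cells the change went along the maturation axis: specific granule genes were lower in blood in 13 of 16 cases with 1 higher (Ltf -2.45 ± 0.32, Camp -1.64 ± 0.22), azurophil genes in 9 of 15 (Fcnb -1.29 ± 0.20). Late maturation genes rose in 13 of 22 (Csf3r +1.86 ± 0.14, Il1b +1.76 ± 0.24). Interferon-stimulated genes rose in 20 of 27 cases with 1 lower (Gbp2 +2.22 ± 0.14, Slfn5 +1.48 ± 0.12), AP-1 genes in 19 of 28 (Junb +1.26 ± 0.12), NF-kB genes in 19 of 30 (Bcl3 +1.10 ± 0.12). Trafficking genes rose in 13 of 22 (Itga4, an integrin chain, +1.2 ± 0.17), hypoxia genes in 16 of 34 (Pfkfb4 +0.63 ± 0.09) and lysosome genes in 15 of 26 (Fabp5 +1.07 ± 0.14). Over the WT maturation peaks 95.7% had the sign of maturation, with a slope of 0.571. In mature cells the interferon list rose in 11 of 27 cases (20 adjusted over the list alone; Gbp2 +1.51 ± 0.15, Oas2 +1.34 ± 0.14, Stat2 +0.81 ± 0.10, n = 2 against 3). This was the one list call of all comparisons that held with an estimated correlation (adjusted p = 0.00512). Erythroid markers were lower in blood in 3 of 13 cases (Slc4a1 -2.75 ± 0.41; adjusted p = 0.253 with an estimated correlation), and Il1r2 was lower (-1.12 ± 0.19). A further 5 lists (azurophil, specific granule, tumour neutrophil, immunosuppression, and monocyte and macrophage markers) were called in mature cells with at most 1 gene past the test each and medians from -0.31 to 0.08, none with fry or with an estimated correlation (adjusted p from 0.253 to 0.84). Nor did fry call the erythroid list. The tumour neutrophil, immunosuppression and monocyte calls were lost with the replicate block (medians -0.04, -0.14 and 0.08) and with peaks within 1 kb (-0.12, -0.10 and 0.155), the monocyte call with the groups fitted alone (0.02), and the tumour neutrophil call with the block within them (-0.025). The tumour neutrophil and immunosuppression calls were lost without marrow library 2 or 3 or blood library 2, and the monocyte call without marrow library 1 or 2 or blood library 2. In immature cells loess offsets ended the AP-1 (0.02), azurophil (-0.37, against -0.43), late maturation (0.24), lysosome (0.145), NF-kB (0.19) and trafficking (0.18) calls, and the groups fitted alone the hypoxia call (0.12). In immature cells 16232 peaks were higher and 13203 lower, in mature cells 384 and 378. The immature list calls were lost with an estimated correlation (adjusted p from 0.408 to 0.526); adjusted over the list alone 14 specific granule genes fell and 20 NF-kB, 20 AP-1 and 16 lysosome genes rose. The hypoxia call was lost without marrow library 1 or blood library 3 (median 0.12 each) and turned to -0.03 with total counts and -0.06 with loess offsets, the lysosome call was lost without marrow library 1 (0.23) and with total counts (0.08), and Fabp5 had -0.31 with peaks within 1 kb of the gene body only. With total counts the splits were 8541 higher and 21298 lower in immature and 276 and 1021 in mature cells, and the mature groups fitted alone gave 4215 peaks, with the block within them 8427. DESeq2 gave 2131 in mature cells and the stricter filter 1152. The mature count was 224 without marrow library 1, 267 without marrow library 3, 47 without blood library 1 and 81 without blood library 2. Il1r2 did not pass without blood library 1 (-1.2) or 2 (-1.04), nor Slc4a1 without blood library 2 (-2.48).

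**Figure D3:**
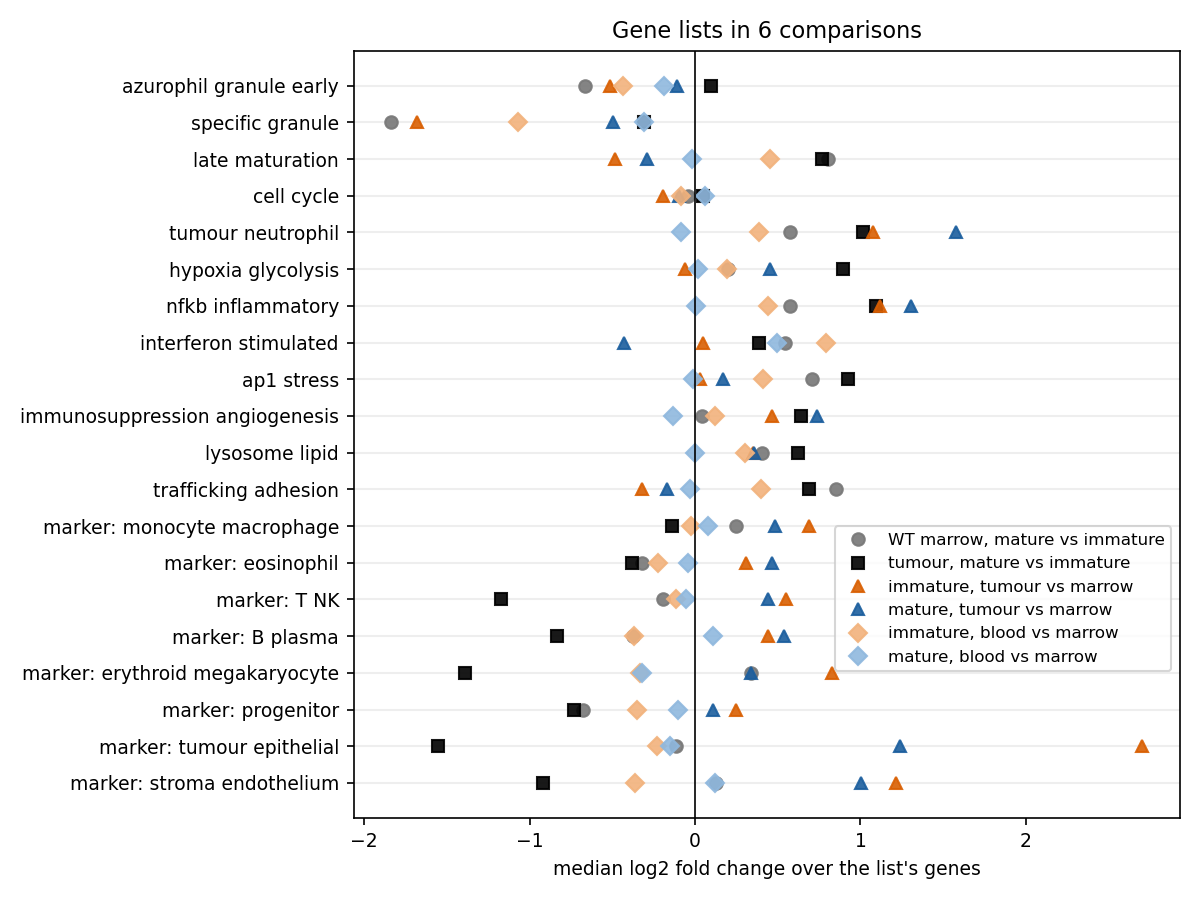
Median log2 fold change of each gene list in 6 comparisons; each point is a list's median over its measured genes, on a linear log2 axis with 0 as no change. The NF-kB list has medians of 1.12 and 1.31 and the tumour epithelium list of 2.70 and 1.24 in immature and mature tumour cells against marrow.

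Marrow of tumour-bearing mice was set against WT marrow to see whether a distant tumour goes with changes at the site of production. In mature cells late maturation genes fell in 4 of 22 cases (10 adjusted over the list alone; Ccl6 -1.60 ± 0.24, Retnlg -1.36 ± 0.26, Fpr1 -0.88 ± 0.24, Sell -0.48 ± 0.14). Hilpda (+0.86 ± 0.18), Bhlhe40 (+0.86 ± 0.12), Ctsb (+0.81 ± 0.11) and Icam1 (+0.49 ± 0.09) rose. In immature cells 3 of 16 specific granule genes fell (8 adjusted over the list alone), namely Camp (-1.0 ± 0.21), Mmp8, a collagenase (-0.99 ± 0.20), and Lyz2, a lysozyme (-0.91 ± 0.18), and Thbs1 fell by 1.5 ± 0.30. Camera called the late maturation list in mature cells, and in immature cells the specific granule list and, with 0 genes past the test each, the late maturation, trafficking and tumour epithelium lists. All were lost with fry and with an estimated correlation (adjusted p of 0.655 in mature, 0.678 and 0.817 in immature cells). In immature cells the late maturation call was also lost without WT library 3 (median -0.07 against -0.17). The tumour epithelium call was lost without tumour-bearing library 1 or 2 or WT library 1 or 2 (0.18 to 0.28), with total counts (0.325) and with peaks within 1 kb of the gene body (0.29), against a main median of 0.28. In immature cells Camp, Lyz2 and Thbs1 did not pass without any 1 of the 3 libraries of tumour-bearing mice or without WT library 2 or 3, and Mmp8 did not without tumour-bearing library 1 or 2 or WT library 2 or 3. In mature cells Fpr1 did not pass without any 1 of the 3 tumour-bearing libraries or WT library 2 or 3 (-0.95 to -0.65), Sell without tumour-bearing or WT library 2 or 3 (-0.50 to -0.36), and Hilpda without tumour-bearing library 3 (+0.67). In the pair of groups fitted alone Camp, Mmp8, Fpr1, Retnlg and Sell did not pass, and with the block within them Icam1, Retnlg and Sell did not. In mature cells 2485 peaks were higher and 2040 lower, in immature cells 482 and 337, and 298 higher and 202 lower peaks were called in both. Calls gathered in 6 windows of 5 Mb on chromosomes 1 and 9, which held 1.66% of the peaks tested. The windows were chosen for an excess of immature calls, so that the 19.66% of these calls they held follows in part from the choice. Of the mature calls, which come from other libraries, they held 4.99%. Camp lies in these windows, near the largest changes, among them peaks at Tmem108 (+7.95 ± 0.34 in immature cells) and Mapkapk3 (-5.24 ± 0.29). Ngp and Ltf, which like Camp belong to the specific granule list, lie in them as well. In immature cells the groups fitted alone gave 2421 peaks, with the block within them 4151, DESeq2 gave 1660, and the peaks off chromosomes 1 and 9 gave 468. Leaving out tumour-bearing library 1, 2 or 3 gave 323, 408 and 326 peaks there, and leaving out WT library 1, 2 or 3 gave 1789, 277 and 252. In mature cells the count was 3006 without tumour-bearing library 2, 1706 without library 3, 2041 without WT library 2 and 1998 without WT library 3. The difference between the maturity effects of tumour-bearing and WT marrow passed at 9 peaks (3 more positive, 6 more negative; 4134 unadjusted, DESeq2 91), of which 5 lay in the same windows. Camera called the cell cycle (median -0.11) and hypoxia (0.10) lists for this difference with 0 genes past the test each, and neither with fry or with an estimated correlation (adjusted p of 0.863). The hypoxia call was lost without immature library 1 or mature library 3 of tumour-bearing mice, without mature library 1 or immature library 3 of WT mice (medians 0.08 to 0.10), and with loess offsets (0.05). The cell cycle call was lost without mature WT library 1 (-0.09). The peak count was 27 without mature WT library 1 and 2 to 4 in 9 of the other 11 omissions of 1 library.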

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

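All tests of explanations and all splits of the libraries in this part were chosen after the results were seen, whereas the differences between maturity effects and the maturation score were planned.

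The effect of maturity differed between tumour and marrow of tumour-bearing mice at 21925 peaks and between the marrow of tumour-bearing and WT mice at 9 peaks, each by a test of the difference itself. In fits of the 12 libraries concerned, the first gave 21819 peaks (as many in 1 of 40 splits, highest other 19112) and the second 13 (as many in 2 of 40 splits, highest other 8083). Random splits mix the effects of maturity and tissue into these contrasts, a structure of the samples, so that neither share tells whether chance explains the count. For the 9 comparisons of 3 libraries against 3 the 10 splits are too few for a share under 0.05. There 1 of 10 splits, the real one, gave as many peaks: 42333, 47329 and 35352 for mature against immature cells in WT marrow, marrow and tumour, 56476 and 46543 for immature and mature tumour against marrow cells, 52080 for immature tumour against blood and 34739 for immature blood against marrow (highest other 0 each), and 2421 and 4742 for immature and mature marrow of tumour-bearing against WT mice (highest other 2 and 0).

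The 2 spleen libraries with contradicting labels gave a signal outside the comparisons, with maturation scores of 1.842 (title immature, cell type mature; 0.076 from the nearest labelled mature spleen library) and -0.061 (title mature, cell type immature; 0.012 from the nearest labelled immature one).

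Markers of tumour epithelium were higher in tumour than in marrow libraries, with medians of 2.70 in immature and 1.24 in mature cells, a difference not called as such (median -0.98), although the CD11b+CD115-Ly6G+ sort would remove such cells. Of the 18 genes, 1 is above the median gene in WT marrow, and the most open ones in immature tumour libraries included Cdh1 (5.54 log2 CPM against 3.15 in marrow), Krt18 (5.32 against 2.11) and Krt19 (4.82 against -1.18). An even background over closed regions would lift all closed genes alike, and against it as the whole cause stands a median 2.15 above that of the T and NK markers (permutation p = 0.02). The permutation exchanges genes, not libraries, so that its p ignores correlation between genes and the spread between libraries. Tumour cells or their DNA in the sorted samples may add to these libraries, since the list's median lay 1.73 above that of genes of like marrow level, at percentile 100 of the sets drawn, while for the markers of stroma, T and NK, B and erythroid cells an even background remains a candidate explanation, as their medians lay at percentile 66.6 or lower of such sets. The share of foreign DNA, GC content and the low depth of the immature tumour libraries stay open, and no biological explanation was tested.

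The tumour neutrophil genes were higher in tumour than in marrow libraries, with medians of 1.07 in immature and 1.58 in mature cells, 1.33 and 1.78 above genes of like marrow level. In the difference between the maturity effects this list had a median of 0.41 and the epithelium markers -0.98 (not called). The gap was 1.39 (permutation p = 4e-05). It cannot decide on tumour cells or their DNA as the whole source, since the lists differ in openness. In WT marrow 17 of the 20 genes are above the median gene, but 1 of the 18 markers. Genes of like marrow level had medians of -0.25 in immature and -0.20 in mature cells for this list, and 0.97 and 0.55 for the markers. Above such genes the list stood higher in mature cells (1.78 against 1.33) and the markers lower (0.69 against 1.73), an order not tested. The permutations here exchange genes, not libraries, so that each p ignores correlation between genes and the spread between libraries. With an estimated correlation the camera call of the tumour neutrophil list in the difference between the maturity effects was lost. Monocytes or macrophages are another possible source, although the CD115- gate would remove them. In mature libraries the tumour neutrophil median lay 1.09 above that of their 17 markers (permutation p = 0.02), of which 6 are above the median gene in WT marrow. The most open of these markers were Adgre1 (6.98 against 6.66 log2 CPM in marrow), Tcf7l2 (6.55 against 6.21) and Cx3cr1 (6.14 against 5.63). The gap weighs against such cells as the whole source only if they would raise both lists alike. Their effect depends on how open a gene is in neutrophils and in those cells, and macrophages were not profiled. A share of such cells is not excluded either, since 10 of the 17 markers rose (Mertk +1.5 ± 0.15, Klf4 +1.19 ± 0.27) and their median lay 0.32 above genes of like marrow level, at percentile 93.45. In immature libraries the 2 lists differed by 0.39 (permutation p = 0.6) and the sources cannot be told apart, since the spread between genes is wide (Tcf7l2 6.86 against 6.10, Klf4 6.10 against 3.45, Adgre1 5.88 against 5.39). A change of the neutrophils themselves in the tumour, which the design names by tissue, may stand behind the rise in mature cells, with GC content and other cell types untested.

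Peaks called between the marrow of tumour-bearing and WT mice lay close together, in 6 windows of 5 Mb on chromosomes 1 and 9 that hold 1.66% of the tested peaks and were chosen for an excess of immature calls (adjusted p under 1e-05), so that their 19.66% of these calls follows in part from the choice, while the mature calls, of other libraries, had 4.99% there (exact hypergeometric p = 2.02e-49). A stretch of genome that differs by strain is a candidate explanation, since mature spleen cells against WT marrow had 2.94% of their calls there (exact hypergeometric p = 2.05e-23) and mature blood cells 3.56%, but mature blood against marrow cells, both of tumour-bearing mice, 1.31% (p = 0.813). The same WT libraries serve in each comparison with WT, and a response of the whole animal to the tumour would also be shared by its tissues. A response spread evenly over the genome would place 1.66% of calls in the windows, and the mature marrow calls had 4.99%. A response need not be even, since Camp, Ngp and Ltf of the specific granule list lie in the windows. Calls between the WT marrow fractions, where Camp and Ltf also fell, had 1.62% there. The shares thus argue only against an evenly spread response to the tumour as the whole cause of the gathering. For the 658 immature calls outside the windows, a response of marrow neutrophils cannot be told apart from strain, as tumour and mouse differ together. The genotypes of the mice were not tested; Ptprc, whose alleles mark some congenic strains, lies in a window on chromosome 1 (138062859 to 138175756).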

How the results depend on the processing

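The stricter filter, the block within the groups compared, the peaks open outside the tumour, the omission of chromosomes 1 and 9, the link within 1 kb, all alternatives for named genes, and those for gene lists except the block, the estimated correlation and fry were chosen after seeing the data; the others were planned. Of 2680 values of 182 named genes under alternatives, 2573 kept direction and side of the threshold, 91 lost the call, 6 gained one and 10 changed sign; for the 130 list calls these numbers were 1742 of 2077, 323, 0 and 12, and 111 of 111 values of 7 peaks kept both. The planned filter removed no peak, so that running without it tested nothing, yet the 182 gene, 130 list and 7 peak values of that run are among those kept. Named peaks and many named genes were picked for a large fold or a small p in the same data, so that the shares kept are no independent check. GC offsets, GC offsets with the block, motif content with its alternatives, and promoter peaks were not run for lack of a genome and of strand. Exact permutation tests of the scores cannot pass 0.05 at these group sizes, and the score differences kept their sign under each alternative, but grew over 1.5 times with the 500 peaks of smallest p in each direction and with a pseudocount of 0.1. On simulated data, with the spread taken over all groups, 36 of 100 peaks changed 2-fold were found with 3 libraries per group and 23 with 2, which limits what a low count shows.

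The stricter filter tested 25000 peaks, fewer by construction. It gave for mature against immature cells 15927 in WT marrow, 16469 in marrow, 16756 in spleen, 7516 in blood and 14472 in tumour of tumour-bearing mice; for immature and mature tumour cells 16072 and 15713 against marrow and 16726 and 15273 against blood; and for blood against marrow 12667 in immature cells. It raised mature blood against marrow to 1152, mature spleen against marrow to 1655 and the difference between maturity effects in marrow to 15, while that in tumour was 7811. The 30132 peaks open outside the tumour, a choice that by construction favours peaks lower in the tumour, gave 24900 and 21381 for immature and mature tumour against marrow and 24274 and 21069 against blood. They gave 20243 between the tumour fractions (16646 higher, 3597 lower) and 11157 for the difference between maturity effects (8565 and 2592), where the main balance leaned to lower peaks. A fold of at least 2, a narrower call by construction, gave 25504 in WT marrow, 24370 in marrow, 5554 in blood, 26344 in tumour, 32053 for mature tumour against marrow, 15324 for immature blood against marrow and 2384 for mature marrow against WT.

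For the alternatives that follow, the cause was not tested. Loess offsets gave 25875 peaks between the tumour fractions, 43 in mature spleen against marrow and 15 for the difference between maturity effects in marrow. Total counts gave 4 in mature spleen and 1297 in mature blood against marrow. The replicate block gave 296 in mature spleen against marrow and 14 for the difference in marrow, and autosomes only gave 32 in mature spleen. The groups compared alone gave 482 in immature and 0 in mature spleen and 4215 in mature blood against marrow, and 2421 in immature marrow against WT. With the block added these were 2116, 1102, 8427 and 4151, with 73 for the difference in marrow. DESeq2 gave 1, 1074, 2131 and 1660, with 91 for that difference. Without chromosomes 1 and 9, immature marrow against WT gave 468 and the difference 0. Of 130 list calls, 1 held with an estimated correlation. Loess offsets ended or turned 58, fry 23, total counts 22, peaks within 1 kb 16, the replicate block, the groups alone and the block within them 8 each, and DESeq2 size factors 2. Apart from fry and the estimated correlation, 113 of these kept their direction, 36 of them with a median at least as large as in the main fit (13 of 17 with total counts), so a lost call is not a lost change.

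Leaving out 1 library left some groups of 2 with a lone library, assumed to vary like the other groups. Between the blood fractions the count ran from 4487 (without mature library 1) to 13656, with 4729 without mature library 2 and 6860 without immature library 1. In mature spleen against marrow it ran from 0 (without marrow library 1 or 3 or spleen library 3; 1 without marrow library 2) to 9530 (without spleen library 1). In mature blood against marrow it ran from 47 (without blood library 1) to 528, with 81 without blood library 2, 224 without marrow library 1 and 267 without marrow library 3. In immature marrow against WT it ran from 252 (without WT library 3) to 1789 (without WT library 1), with 277 without WT library 2 and 323, 408 and 326 without libraries 1, 2 and 3 of tumour-bearing mice. In mature marrow against WT it ran from 1706 (without tumour-bearing library 3) to 6129, with 3006 without tumour-bearing library 2, 2041 without WT library 2 and 1998 without WT library 3. The difference between maturity effects in marrow ran from 2 to 27 (without mature WT library 1), with 2 to 4 without any of the other libraries but mature tumour-bearing library 1 and immature WT library 3. List calls ran from 124 to 143, and the other counts moved by less than 1.5 times.

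Some directions changed. With total counts the hypoxia median was -0.049 in marrow and -0.068 in spleen (mature against immature) and -0.027 in immature blood against marrow, the interferon median -0.029 between the tumour fractions and -0.028 in mature spleen against marrow, and Cd101 -0.178 in WT marrow. With loess offsets the hypoxia medians were -0.081, -0.015 and -0.058, the T and NK median of immature tumour against blood -0.237, Vegfa between the tumour fractions -0.061, Cd101 -0.138 and Itgam in mature tumour against blood 0.064. Csf1r in immature tumour against blood ran from -0.037 (without immature blood library 1) to 0.192 leaving out libraries. With peaks within 1 kb Cd101 was -0.076, Fabp5 in immature blood against marrow -0.306 and Ltf between the tumour fractions 0.144. Ltf was 0.034 with the block within the groups, and leaving out libraries it ran from -0.417 to 0.609 (without immature tumour library 2). The tumour neutrophil median of mature blood against marrow ran from -0.141 to 0.002 (without marrow library 3). In mature spleen against marrow the cell cycle median ran from -0.277 to 0.026 (without spleen library 3) and the interferon median from -0.031 (without spleen library 1) to 0.249. Ltf, Cd101, Itgam and Csf1r had no call to lose there.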

Other observations

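Of the 4 genes of the sort markers, 2 were less accessible in the tumour in every comparison. Cd101 was lower in tumour than in marrow, with -1.01 ± 0.11 in immature and -0.73 ± 0.11 in mature cells (log2 fold change ± SE, n = 3 per group; adjusted p of 5.09e-08 and 5.64e-06), and Ly6g likewise, with -1.39 ± 0.14 and -1.09 ± 0.14. Against blood, Cd101 had -0.98 ± 0.11 and -0.59 ± 0.12, and Ly6g -1.31 ± 0.14 and -0.90 ± 0.15. These 8 differences kept direction and call in each alternative tried for named genes. A fall was not particular to these genes. Peaks open outside the tumour, a choice that favours lower ones, had medians of -0.832 in immature and -0.514 in mature cells against marrow. Against blood these medians were -0.949 and -0.562. The other 2 genes of the sort markers, chosen after their values were seen, did not move together. Against marrow Itgam, the gene of CD11b, had -0.44 ± 0.10 and -0.31 ± 0.10, whereas Csf1r, the gene of CD115, had +0.69 ± 0.12 and +0.30 ± 0.11. Against blood Itgam had -0.77 ± 0.10 and -0.21 ± 0.11 (the latter not past the test) and Csf1r +0.10 ± 0.12 (not past the test) and +0.30 ± 0.13. Loess offsets turned Itgam in mature cells against blood to +0.064, and several calls of the 2 genes were lost under alternatives. Between the CD101+ and CD101- fractions of one tissue, Cd101 did not pass the test in any of the 5 comparisons, with values from -0.31 in spleen to +0.23 in the tumour.

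Ltf and Mpo were more open in mature tumour cells than in mature blood cells, at +2.21 ± 0.38 and +1.51 ± 0.17 (n = 3 against 2), and these calls held in each alternative. Granule genes at large did not move so: the specific granule list had 4 genes higher and 6 lower of 16, the azurophil list 5 and 2 of 15, and neither was called. Over the 25504 maturation peaks of WT marrow, the change from immature marrow to immature tumour cells had the sign of maturation in 73% with a slope of 0.585, and that from immature blood to immature tumour cells in 41.3% with a slope of 0.014. Of the peaks that rose with maturity in WT marrow, 12438 also rose between the tumour fractions, against 5023.2 expected if calls were independent, and of those that fell 7008 against 4641.1; peaks are not independent replicates.

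The first principal component of log2 CPM held 51.3% of the variance and set the 6 tumour libraries, at -443.3 to -274.1, apart from the other 21, at -87.6 to 192.2. Mature spleen library 3 was the lowest of these 21. It had 6.89% of its counts outside the primary chromosomes, against 3.74% in library 1, and a tumour score of -2.01 against -2.46. The 3 immature blood libraries spread more on the maturation score than those of any other group, from 0.86 to 1.31.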
